A study of Danio rerio with 25 samples.

How the data were processed

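Poly(A) RNA was sequenced from testes of zebrafish (Danio rerio) after cardiac cryoinjury, in which part of the heart ventricle is killed by freezing, and from uninjured males. Per the labels, each library was made from the pooled testes of 4 sibling males with a stranded TruSeq kit, so each replicate is a separate pool of fish. The 25 libraries came from 2 experiments. Experiment 1, with paired reads of 51 bases, held uninjured replicates 1 to 5 and 5 libraries each at 7 and 130 days post injury (dpi). Experiment 2, with paired reads of 151 bases, held uninjured replicates 6 to 10 and 5 libraries at 1 dpi. Experiment, read length and fish cohort were therefore confounded with each other, and uninjured libraries were the only group present in both.

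The deposited table held whole-number counts of reads per gene, not normalized, for 32520 Ensembl genes, of which 29201 carried a name. Per the file headers, it was merged from 1 count table of each batch, its columns were renamed, and the position and length columns were dropped. The submitters' processing notes name FastQC 0.11.9, MultiQC 1.12, STAR 2.7.10a, featureCounts of Subread 2.0.3, R 4.4.0, DESeq2 1.44.0 and the zebrafish genome build GRCz11. The annotation release and the strand setting of the count are not given in the sources used here, so reads of near-identical gene copies and of overlapping genes on opposite strands are uncertain. No genome sequence or coordinate was used here. Gene symbols are those of the table, which writes 12593 names in capitals and gives some symbols to several gene copies, so that the Ensembl identifier stands beside each named gene once. Per the labels, 130 dpi replicate 5 stood apart in a principal component analysis and was left out downstream, and the experiments were combined after batch correction.

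Every column of the table was used, and the counts were taken as deposited. Total counts per library were lowest in 1 dpi replicate 2, at 28.53 M, and at least 45.6 M in every other library. For each of the 50 pairs of libraries within a group the counts were compared by chi-square, which ranged from 10.2 to 113 per degree of freedom, so no library was counted as a repeat of another. The analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The main test was edgeR's quasi-likelihood test (robust fit) with trimmed mean of M-values normalization on the 26648 genes that passed edgeR's expression filter, over 24 libraries without 130 dpi replicate 5, with experiment and condition as terms. Each injured group was thereby compared with the uninjured libraries of its own experiment, while all libraries shared 1 estimate of the spread. The direct contrast of 130 dpi with 7 dpi, the difference of the changes at 1 and 7 dpi, and the difference of the uninjured groups came from the same fit. Adjusted p-values are Benjamini-Hochberg values over all genes tested, the threshold was 0.05, and all tests were two-sided. Levels are counts per M (CPM) with the normalized library size, given as mean and SD; log2 fold changes are given with a standard error, computed as the absolute log2 fold change over the square root of the F statistic.

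Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over 31 lists, beside camera with a correlation estimated for each list and the rotation test fry. The lists held 1105 written members for signalling, stress, cell type, tissue and housekeeping groups; 973 matched a gene of the table, and 39 were left out because the symbol was ambiguous. Levels of a list in a library are means of its members' log2 CPM, with 2 counts added, less the mean of the uninjured libraries of that experiment. Libraries counted as lower or higher in a list lie on that side of the uninjured mean and can still lie within the uninjured range. The design, the named-gene rule, the lists and the alternatives named below, except where stated, were fixed before the data were examined. By the rule, the text names per injured group the 10 genes with the largest increase and the 10 with the largest decrease among those past the test, with a mean of at least 1 CPM, a symbol that is not clone-based, and every injured library on the same side of the uninjured mean. Where fewer passed, those that passed are named, and where none passed the 5 with the smallest p, as not past the test. Up to 4 members of each list described, those with the smallest p, and a fixed set of cytokine, steroid and germ cell genes were added. Of the genes met by the rule or as list members, some are not reported here, although they stay in the counts of genes and lists called. Any other gene named was chosen after its values were seen.

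The tests were tested on simulated counts for the 26648 genes, with 67 genes changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold. At 1 dpi edgeR recovered 52.2, 76.1 and 98.5% of them, at 7 dpi 56.7, 83.6 and 97%, and at 130 dpi 53.7, 83.6 and 95.5%, in that order of fold. Unchanged genes made up 3.64% of the edgeR calls at 1 dpi, 5.56% at 7 dpi and 6.25% at 130 dpi, and for DESeq2 12.4, 17.9 and 16.6%. For voom these shares were 3.57, 6.56 and 6.36%. The changed genes were drawn among the better counted ones, so the shares recovered need not hold for genes with few counts. Each gene was drawn on its own, with the spread that edgeR had estimated. The simulation therefore held no structure between libraries, and its shares of false calls need not hold for the real libraries.

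The alternatives were DESeq2, limma voom with quality weights, upper-quartile factors, no filter or a filter of 1 CPM in 5 libraries, all 25 libraries, libraries of 1 experiment only, a fit that was not robust, a minimum of 2-fold, the replicate number as a block, and leaving out each library in turn. After the data were examined, fits without the 4 libraries richest in digestive-tissue RNA and with the level of those markers as a covariate were added. These 4 were uninjured replicate 1, 7 dpi replicate 4 and 130 dpi replicate 3 of experiment 1 and uninjured replicate 10 of experiment 2. Marker lists of liver transcripts outside the acute phase list, exocrine pancreas, intestine, oxidative phosphorylation subunits and 2 phases of the circadian clock were also written after the data were examined. Up to 100 regroupings of the libraries were drawn for each count of genes or lists.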

Results

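Testis RNA was measured in zebrafish at 1, 7 and 130 days after cardiac cryoinjury (days post injury, dpi), a freezing wound of the ventricle that this species repairs by regrowing heart muscle. The question was how gene expression in the gonad changes with time after damage to the heart. Experiment 1 held 5 uninjured libraries with at least 70.5 M counts, 5 libraries at 7 dpi with 71.4 to 86.7 M and 5 at 130 dpi with 65.4 to 81.7 M. Experiment 2 held 5 other uninjured libraries with 45.6 to 55.1 M counts and 5 libraries at 1 dpi with up to 56.8 M. The comparisons used 4 of the 5 libraries at 130 dpi.

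The uninjured testes of the 2 experiments differed widely. Genes of cytosolic ribosomal proteins, which build the translation machinery, were higher in experiment 2, with a median log2 difference of 0.35 and 63 of 80 members higher past the test (camera adjusted p = 3.06e-11; adjusted p = 0.534 with an estimated correlation). Circadian clock genes were lower, with a median of -0.44 and 28 of 37 members lower past the test (camera adjusted p = 4.81e-07; adjusted p = 0.519 with an estimated correlation). Among all genes tested, 6668 were higher and 7176 lower in experiment 2 by edgeR's quasi-likelihood test. Read length and cohort differed between the experiments, so each injured group was set against the uninjured libraries of its own experiment.

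At 1 dpi HSD11B2 (ENSDARG00000001975), the enzyme that inactivates cortisol and takes part in androgen synthesis in the fish testis, rose from 109 ± 32.9 to 305 ± 63.1 CPM (SD, n = 5 each). The log2 change was 1.49 ± 0.21 (SE), all 5 injured libraries lay above all 5 uninjured ones, and it was the 1 gene of 26648 past edgeR's test (adjusted p = 0.0209). In the uninjured testes of experiment 1 it averaged 219 CPM (185 to 281), a range that overlapped that of 1 dpi (224 to 375). The glucocorticoid response list, genes induced by cortisol, rose with a median log2 change of 0.18 over 21 members and a mean above the uninjured mean in 5 of 5 libraries (camera adjusted p = 9.75e-05; adjusted p = 0.158 with an estimated correlation). HSD11B2 was its 1 member past the test over all genes and the 1 adjusted over the list alone. Among the other members, FKBP5 (ENSDARG00000028396), a co-chaperone of the glucocorticoid receptor, measured 85.0 ± 43.7 against 25.7 ± 24.1 CPM (log2 1.73 ± 0.61, edgeR adjusted p = 0.473). KLF9 (ENSDARG00000068194), a transcription factor induced by cortisol, measured 26.9 ± 6.01 against 18.7 ± 4.12 CPM (adjusted p = 0.46). At an unadjusted p below 0.05 there were 2011 genes, where 1332 are expected by chance. The call of HSD11B2 ended without 1 dpi replicate 4, 1 dpi replicate 5, uninjured replicate 7 or uninjured replicate 9 of experiment 2 (0 genes each; largest adjusted p = 0.0981, without 1 dpi replicate 5). It also ended with the libraries of experiment 2 alone (adjusted p = 0.193), where 9 other genes passed. The count became 45 without uninjured replicate 8, 4 without 1 dpi replicate 1, 2 without 1 dpi replicate 3, uninjured replicate 6 or uninjured replicate 10, and by tool 82 with DESeq2 and 4 with voom.

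Markers of macrophages, the tissue phagocytes, fell at 1 dpi with a median log2 change of -0.20 and a lower mean in 3 of 5 libraries (camera adjusted p = 0.000793; adjusted p = 0.844 with an estimated correlation). None of the 30 members passed edgeR's test over all genes or adjusted over the list alone, and 1 had an unadjusted p below 0.05. MFAP4 (ENSDARG00000090783), whose zebrafish copies include macrophage markers, measured 2.77 ± 0.43 against 11 ± 3 CPM and lay below every uninjured library in 5 of 5, without passing the test (log2 -1.99 ± 0.34, adjusted p = 0.0608). The other 4 genes with the smallest p among those lower were NR2F6 (ENSDARG00000003165), ZNF395 (ENSDARG00000060113), REL (ENSDARG00000055276) and ZFAND2B (ENSDARG00000103511), with adjusted p from 0.127 to 0.201. The list of acute phase and complement genes, plasma proteins of the liver, fell with a median of -0.85 and a lower mean in 3 of 5 libraries (camera adjusted p = 0.00946; adjusted p = 0.844 with an estimated correlation). Of its 25 members 0 passed edgeR's test and 1 had an unadjusted p below 0.05. Liver transcripts outside that list had a median of -0.37, with 29 of 32 negative. The macrophage call ended without 1 dpi replicate 4 (adjusted p = 0.141) or uninjured replicate 8 of experiment 2 (0.106). The acute phase call ended without 1 dpi replicate 4 (0.12), 1 dpi replicate 5 (0.0576), uninjured replicate 6 (0.135) or uninjured replicate 10 (0.498), without the 4 libraries richest in digestive-tissue RNA (0.399), and with the level of digestive-tissue markers as a covariate (0.0705). The macrophage median became -0.11, -0.315 and -0.09 without 1 dpi replicate 4, 1 dpi replicate 5 and uninjured replicate 8. The acute phase median became -0.23 without uninjured replicate 10, -0.24 without the 4 libraries and -0.36 with the covariate.

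The list of Leydig cells, which make androgens, rose at 1 dpi by camera with a median log2 change of 0.10 (camera adjusted p = 0.0165; adjusted p = 0.844 with an estimated correlation). Sertoli cell markers, of the cells that nurse the germ cells, rose with 0.10 (camera adjusted p = 0.0165; adjusted p = 0.844 with an estimated correlation). Genes of spermatids and sperm rose with 0.05 (camera adjusted p = 0.0165; adjusted p = 0.861 with an estimated correlation). Each of the 3 had a higher mean in 5 of 5 libraries, of which 3, 4 and 0 in that order lay above every uninjured library. No member of these lists passed edgeR's test over all genes, and 5 of 25, 2 of 21 and 1 of 57 had an unadjusted p below 0.05. Adjusted over the list alone 1 passed, the Sertoli cell growth factor igf3 (ENSDARG00000058058, 3.53 ± 1.61 against 0.987 ± 0.746 CPM). CYP17A1 (ENSDARG00000033566), a steroid hydroxylase of androgen synthesis, measured 254 ± 29.6 against 182 ± 54.7 CPM (adjusted p = 0.549). The Leydig hormone gene insl3 (ENSDARG00000035862) measured 4010 ± 568 against 2720 ± 903 CPM (adjusted p = 0.656). The cytokine gene il1b (ENSDARG00000098700) was at 29.8 ± 5.78 against 30.9 ± 5.35 CPM (adjusted p = 0.98). The Leydig call ended without 1 dpi replicate 3 (adjusted p = 0.0901) or uninjured replicate 9 (0.48). The Sertoli call ended without 1 dpi replicate 1 (0.0513), 1 dpi replicate 3 (0.0854) or uninjured replicate 9 (0.135). The spermatid call ended without 1 dpi replicate 4 (0.0734), 1 dpi replicate 5 (0.0623), uninjured replicate 7 (0.226), uninjured replicate 8 (0.195) or uninjured replicate 9 (0.062), and with digestive-tissue markers as a covariate (0.0705). The Leydig median became 0.04, 0.06, 0.165 and 0.00 without 1 dpi replicates 2 and 3 and uninjured replicates 6 and 9, and the Sertoli median 0.05 without uninjured replicate 9. The spermatid median became 0.02, 0.03 and 0.09 without uninjured replicates 7, 8 and 10, and 0.08 without the 4 libraries richest in digestive-tissue RNA.

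**Figure D1:**
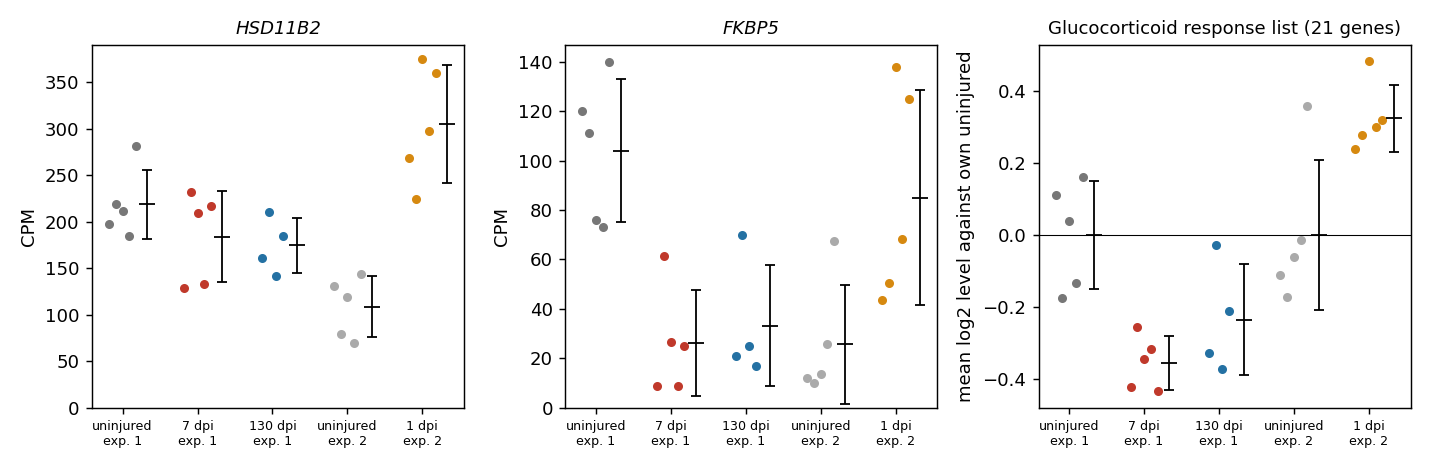
Levels in CPM of HSD11B2 and FKBP5 and the mean log2 level of the glucocorticoid response list, less the mean of the uninjured libraries of the same experiment, in each library (points; bars, mean and SD). All 5 libraries at 1 dpi lie above the 5 uninjured libraries of experiment 2 in HSD11B2, while the list lies below all 5 uninjured libraries of experiment 1 in 5 of 5 libraries at 7 dpi.

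At 7 dpi 326 genes changed past edgeR's test, 104 up and 222 down. MYCN (ENSDARG00000006837), a transcription factor of cell growth, rose from 3.91 ± 0.45 to 11.7 ± 1.68 CPM (SD, n = 5 each; log2 1.58 ± 0.20, adjusted p = 0.000418). The interferon lambda receptor gene ifnlr1 (ENSDARG00000087131) rose from 7.05 ± 2.68 to 15.8 ± 3.28 CPM (log2 1.16 ± 0.23, adjusted p = 0.0126). The gene tsc22d3 (ENSDARG00000075666), a mediator of glucocorticoid action, fell from 79.1 ± 9.96 to 23.3 ± 7.64 CPM (log2 -1.76 ± 0.31, adjusted p = 0.00628). GADD45B (ENSDARG00000027744), a stress-induced growth arrest gene, fell from 60.0 ± 16.5 to 15.5 ± 8.41 CPM (log2 -1.96 ± 0.34, adjusted p = 0.00606). CSRNP1 (ENSDARG00000038429), an early response transcription factor, fell from 25 ± 12.1 to 7.64 ± 2.23 CPM (log2 -1.71 ± 0.28, adjusted p = 0.00379). A small GTPase gene induced by glucocorticoids, rasd1 (ENSDARG00000019274), fell from 5.67 ± 4.11 to 1.37 ± 0.62 CPM (log2 -2.05 ± 0.40, adjusted p = 0.0116). In the uninjured testes of experiment 2, tsc22d3, GADD45B, CSRNP1 and rasd1 averaged 37.8, 22.3, 6.76 and 1.2 CPM, also below those of experiment 1. MYCN averaged 6.54 CPM there, and ifnlr1 ranged from 18 to 30 CPM, both above the uninjured testes of experiment 1. For ifnlr1 that range reached above the libraries at 7 dpi (11.5 to 19.5 CPM). The other increases by the rule were itih3b.2 (ENSDARG00000100406), slc7a2 (ENSDARG00000037097), kcnh6b (ENSDARG00000010296), slc25a24l (ENSDARG00000038977), RBFOX3 (ENSDARG00000074310), sned1 (ENSDARG00000044433) and tex2l (ENSDARG00000078132), with log2 changes from 1.02 to 2.79 and adjusted p from 0.0163 to 0.0489. The other decreases were NTS (ENSDARG00000057887, neurotensin), ppp1r14d (ENSDARG00000110496), GADD45G (ENSDARG00000019417), the clock repressor gene nr1d2a (ENSDARG00000003820), the kinase gene NUAK1 (ENSDARG00000020086) and fxyd2 (ENSDARG00000094561), with log2 changes from -3.18 to -1.76 and adjusted p from 0.0127 to 0.0359. Levels were low and the uninjured spread wide for NTS (0.414 ± 0.175 against 3.75 ± 4.12 CPM), ppp1r14d (0.305 ± 0.124 against 1.75 ± 1.39) and fxyd2 (0.928 ± 0.412 against 3.16 ± 2.04). NTS and ppp1r14d each lay below every uninjured library in 3 of 5 libraries at 7 dpi. Of the 326 genes, 39 rose and 69 fell at least 2-fold, the median absolute log2 change was 0.72, and 3852 genes had an unadjusted p below 0.05.

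Of the genes named by the rule at 7 dpi, MYCN, ifnlr1, ppp1r14d, rasd1, GADD45B, tsc22d3 and CSRNP1 passed the test without any 1 library. The other 12 lost it without at least 1, with a largest adjusted p from 0.0544 for sned1 (without uninjured replicate 1) to 0.186 for slc7a2 (without 7 dpi replicate 4). With experiment 1 alone 15 of the 19 lost it, with adjusted p from 0.0661 for slc25a24l to 0.182 for slc7a2. Without the 4 libraries richest in digestive-tissue RNA 14 lost it, from 0.0601 for ifnlr1 to 0.207 for kcnh6b. MYCN, GADD45B, tsc22d3 and CSRNP1 passed in every alternative. Of the list members below, SOCS3, DHX58, CMPK2, CEBPB, DUSP1, JUN, SYCP1, TEX11, mov10b.1 and a2ml lost it with experiment 1 alone (adjusted p from 0.0512 for DHX58 to 0.158 for a2ml). Without 7 dpi replicate 4 the log2 changes of itih3b.2, a plasma protein gene of the liver, and slc7a2, an arginine transporter gene, were 1.35 and 0.86, against 2.79 and 1.95 with it. The count of 326 became 1167 without uninjured replicate 5 of experiment 1, 156, 149 and 154 without uninjured replicates 1, 2 and 3, and 153, 181, 143 and 173 without 7 dpi replicates 2, 3, 4 and 5. It was 1019 with DESeq2, 1215 with voom, 208 with all 25 libraries, 89 with experiment 1 alone and 81 without the 4 libraries richest in digestive-tissue RNA.

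**Figure D2:**
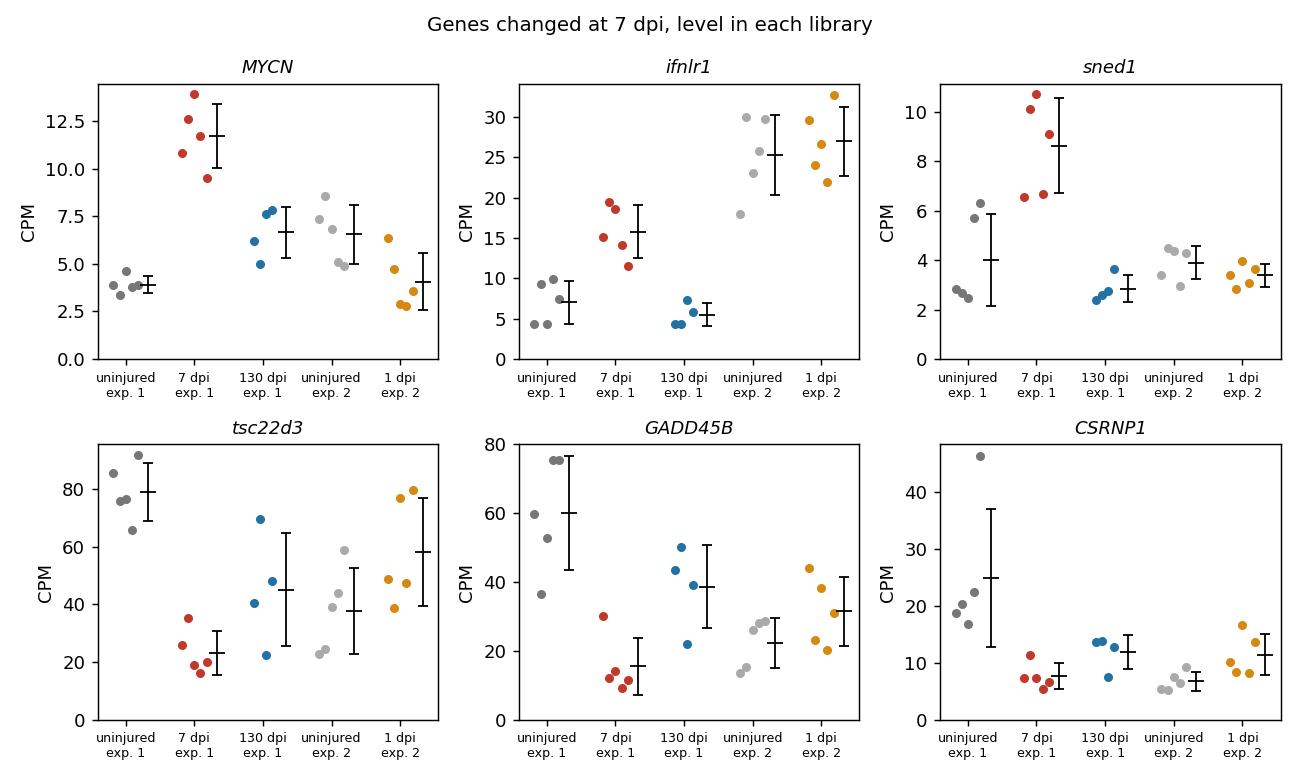
Levels in CPM of MYCN, ifnlr1, sned1, tsc22d3, GADD45B and CSRNP1 in each library of the 5 groups (points; bars, mean and SD). MYCN averages 11.7 CPM at 7 dpi against 3.91 in the uninjured libraries of experiment 1 and 6.54 in those of experiment 2.

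The immediate early, glucocorticoid, interferon and JAK-STAT lists fell at 7 dpi by camera. Immediate early genes, transcription factors switched on within minutes of a stimulus, had 0 of 32 members up and 4 down past the test, and 0 up and 9 down adjusted over the list alone. Their median was -0.09, with a lower mean in 5 of 5 libraries (camera adjusted p = 3.71e-05; adjusted p = 0.37 with an estimated correlation). Examples were JUND (ENSDARG00000067850) at 21.3 ± 1.78 against 28.7 ± 1.24 CPM, klf2a (ENSDARG00000042667) at 31.6 ± 0.76 against 43.7 ± 6.17 and JUN (ENSDARG00000043531) at 19.1 ± 3.75 against 35.0 ± 11.7. The glucocorticoid response list had 0 of 21 members up and 4 down, and 1 up and 8 down adjusted over the list alone. It had a median of -0.17 and a mean below every uninjured library in 5 of 5 (camera adjusted p = 3.71e-05; adjusted p = 0.173 with an estimated correlation). CEBPD (ENSDARG00000087303) and CEBPB (ENSDARG00000042725), transcription factors of the acute stress response, fell to 19.6 ± 5.89 from 52.2 ± 16.0 and to 10.8 ± 1.45 from 24.6 ± 0.92 CPM. The phosphatase gene DUSP1 (ENSDARG00000100515) fell to 39.0 ± 6.83 from 61.0 ± 13.9 CPM. The interferon response list, antiviral genes, had 0 of 36 members up and 3 down, and 1 up and 12 down adjusted over the list alone. It had a median of -0.18 and a lower mean in 4 of 5 libraries (camera adjusted p = 6.94e-06; adjusted p = 0.585 with an estimated correlation). The antiviral GTPase gene mxe (ENSDARG00000014427) fell to 16.4 ± 2.54 from 29.7 ± 2.15 CPM (log2 -0.85 ± 0.10, adjusted p = 0.000378), and DHX58 (ENSDARG00000089463), an RNA sensor, and CMPK2 (ENSDARG00000031359) by 0.60 and 0.55 on the log2 scale. JAK-STAT genes, which carry cytokine signals, had 0 of 29 members up and 5 down, and 0 up and 7 down adjusted over the list alone. They had a median of -0.03 and a lower mean in 5 of 5 libraries (camera adjusted p = 0.00293; adjusted p = 0.598 with an estimated correlation). One SOCS3 copy (ENSDARG00000025428), a feedback inhibitor of that pathway, fell to 40.5 ± 7.92 from 99.0 ± 30.6 CPM. The transducer gene stat2 (ENSDARG00000031647) fell to 443 ± 18.8 from 575 ± 18.2 and the survival gene mcl1b (ENSDARG00000008363) to 60.2 ± 5.67 from 86.6 ± 6.72. The other SOCS3 copy (ENSDARG00000026611) was at 21.5 ± 1.02 against 20 ± 2.21 CPM (adjusted p = 0.878). These 4 calls held without each of the 10 libraries in turn, but the JAK-STAT median changed sign. It was 0.01 without 7 dpi replicate 5 and 0.03, 0.00 and -0.055 without uninjured replicates 4, 5 and 2, and -0.04 without the 4 libraries richest in digestive-tissue RNA and -0.015 with the replicate number as a block. The immediate early median became -0.17 without 7 dpi replicate 1 and -0.15 and -0.16 without uninjured replicates 1 and 5. The glucocorticoid median became -0.09 and -0.27 without uninjured replicates 1 and 4, and the interferon median -0.11 without uninjured replicate 5. Without the 4 libraries the last 2 were -0.09 and -0.12.

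Inflammatory cytokines and NF-kB targets also fell at 7 dpi, with 0 of 38 members up and 1 down, and 0 up and 3 down adjusted over the list alone. They had a median of -0.20 and a lower mean in 4 of 5 libraries (camera adjusted p = 0.00254; adjusted p = 0.68 with an estimated correlation). The called member was nfkbiab (ENSDARG00000007693), an inhibitor of NF-kB that NF-kB itself induces, at 32.5 ± 4.49 against 67.7 ± 10.4 CPM (log2 -1.06 ± 0.15, adjusted p = 0.000963). The cytokine il1b stayed at 27.9 ± 1.24 against 27.8 ± 3.21 CPM (adjusted p = 0.995). The cytokine tnfa (ENSDARG00000009511) was at 0.0712 ± 0.0458 against 0.709 ± 0.656 (adjusted p = 0.0917). The cytokine il6 (ENSDARG00000102318) was at 0.159 ± 0.0825 against 0.176 ± 0.0794 CPM (adjusted p = 0.942). The chemokine gene cxcl8a (ENSDARG00000104795) was at 0.367 ± 0.151 against 0.733 ± 0.511 CPM (adjusted p = 0.51). Macrophage markers fell with a median of -0.21 and a lower mean in 4 of 5 libraries (camera adjusted p = 0.0154; adjusted p = 0.832 with an estimated correlation). Of 30 members 0 passed edgeR's test or adjusted over the list alone, and 2 had an unadjusted p below 0.05. Erythrocyte markers fell with a median of -0.32 and a lower mean in 5 of 5 libraries (camera adjusted p = 0.000868; adjusted p = 0.598 with an estimated correlation). Among 16 members 1, the red cell spectrin gene SPTB (ENSDARG00000030490; 19.3 ± 0.90 against 27.2 ± 1.62 CPM), fell past both adjustments. Without the 4 libraries richest in digestive-tissue RNA the inflammatory call ended (adjusted p = 0.0859), as did the macrophage call (0.26). The macrophage call also ended without 7 dpi replicate 3 (0.0612), 7 dpi replicate 4 (0.0817), uninjured replicate 1 (0.0955) or uninjured replicate 3 (0.528), and the erythrocyte call without uninjured replicate 5 (0.135). The inflammatory median became -0.13 without uninjured replicate 1 and -0.12 without the 4 libraries. The macrophage median became -0.32 and -0.06 without 7 dpi replicate 1 and uninjured replicate 3, and the erythrocyte median -0.16 without uninjured replicate 5.

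Among germ cell genes, the meiosis list fell at 7 dpi with a median of -0.10 and a lower mean in 5 of 5 libraries (camera adjusted p = 4.42e-05; adjusted p = 0.598 with an estimated correlation). It had 0 of 33 members up and 2 down past the test, and 1 up and 4 down adjusted over the list alone. SYCP1 (ENSDARG00000003904), a strand of the synaptonemal complex, fell to 1510 ± 102 from 1900 ± 265 CPM (log2 -0.34 ± 0.08, adjusted p = 0.0346). TEX11 (ENSDARG00000078995), a meiotic crossover gene, fell to 209 ± 21.8 from 255 ± 15.2 CPM (adjusted p = 0.0463). The meiotic recombinase gene DMC1 (ENSDARG00000055883) was at 201 ± 16.0 against 259 ± 46.4 CPM (adjusted p = 0.0623), and SYCP3 (ENSDARG00000013438) at 453 ± 25.9 against 499 ± 54.7 CPM (adjusted p = 0.399). The piRNA pathway, which silences transposons in germ cells, rose with a median of 0.08 (camera adjusted p = 0.0154; adjusted p = 0.598 with an estimated correlation). Its mean was higher in 5 of 5 libraries, and above every uninjured library in 0. Its 1 member past the test, the helicase gene mov10b.1 (ENSDARG00000061177), fell to 31.9 ± 1.78 from 41.0 ± 3.52 CPM. Adjusted over the list alone 1 member was up, PIWIL2 (ENSDARG00000062601; 432 ± 27.9 against 359 ± 43.6 CPM), and 1 down. The Leydig list fell with a median of -0.14 and a lower mean in 5 of 5 libraries (camera adjusted p = 0.0371; adjusted p = 0.809 with an estimated correlation). Of 25 members 0 passed edgeR's test and 5 had an unadjusted p below 0.05, and 1, the electron donor gene FDXR (ENSDARG00000089369; 50.8 ± 5.50 against 79.6 ± 23.3 CPM), was down adjusted over the list alone. The piRNA call ended without uninjured replicate 1 (adjusted p = 0.0955), and the Leydig call without 7 dpi replicate 1 (0.15), 7 dpi replicate 4 (0.0654) or uninjured replicate 5 (0.387). Without the 4 libraries richest in digestive-tissue RNA the piRNA (0.127) and Leydig (0.0549) calls ended and the meiosis median was -0.16. The Leydig call also ended with digestive-tissue markers as a covariate (0.0536), and its median was -0.095 without uninjured replicate 3.

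Acute phase and complement genes, which encode plasma proteins made by the liver, rose at 7 dpi with a median log2 change of 2.33 (camera adjusted p = 0.000523; adjusted p = 0.809 with an estimated correlation). Of 25 members 1 was up past the test, and 17 up and 2 down adjusted over the list alone. The called member was a2ml (ENSDARG00000056314), a protease inhibitor gene, at 8.24 ± 13.8 against 0.69 ± 0.13 CPM (adjusted p = 0.0461). The fibrinogen gene FGB (ENSDARG00000008969) was at 60.6 ± 105 against 5.81 ± 1.56 CPM (adjusted p = 0.0849). The mean of the list lay above every uninjured library of experiment 1 in 3 of 5 libraries, by 3.43 over the uninjured mean in 7 dpi replicate 4, 1.58 in replicate 5 and 0.39 in replicate 1. Liver transcripts outside the list moved with it, at a median of 2.24 with 30 of 32 positive and levels of 4.03 in replicate 4 and 1.82 in replicate 5. The call ended without 7 dpi replicate 4 (adjusted p = 0.0874, median 0.42) and without the 4 libraries richest in digestive-tissue RNA (0.114, median 0.38). The median was 1.08 with the replicate number as a block and 1.29 with the level of digestive-tissue markers as a covariate.

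**Figure D3:**
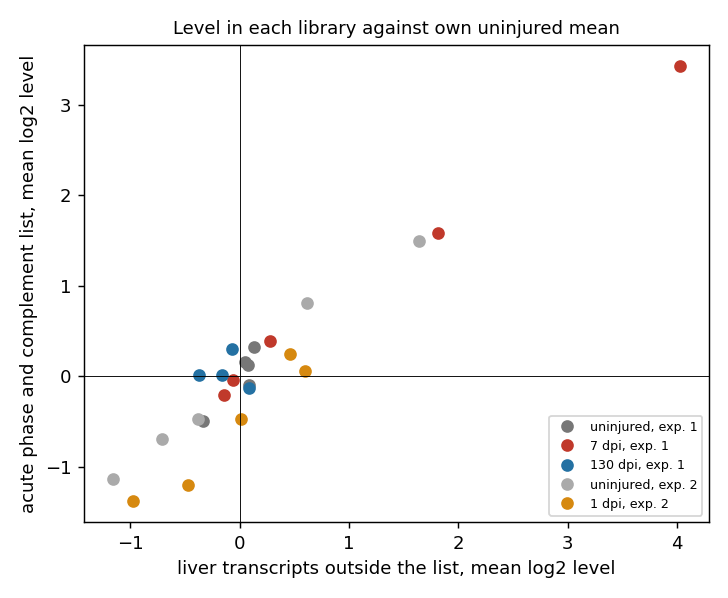
Mean log2 level of the acute phase and complement list against that of liver transcripts outside the list in each library, less the mean of the uninjured libraries of the same experiment (points, coloured by group). The libraries of 7 dpi replicates 4 and 5 lie at 4.03 and 1.82 on the horizontal axis and 3.43 and 1.58 on the vertical axis.

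At 130 dpi no gene passed edgeR's test (0 of 26648, smallest adjusted p = 0.0947), but mRNAs of cytosolic ribosomal proteins were lower almost as a whole. Of these 80 genes 79 had a negative log2 change, and the median was -0.20. Of these, 67 were down and 0 up adjusted over the list alone, with a lower mean in 4 of 4 libraries (camera adjusted p = 5.16e-56; adjusted p = 0.0533 with an estimated correlation). The mean lay below every uninjured library in 3 of them. In 130 dpi replicate 3 it was -0.02, within the uninjured range of -0.04 to 0.03. RPS13 (ENSDARG00000036298) was at 271 ± 15.8 CPM (SD, n = 4) against 322 ± 11 (n = 5; log2 -0.25 ± 0.05, adjusted p = 0.194). RPL7 (ENSDARG00000007320) was at 719 ± 44.5 against 840 ± 22.5 (0.229) and RPL10 (ENSDARG00000025581) at 481 ± 54.0 against 574 ± 16.0 (0.229). The mRNAs encoded by mitochondrial DNA fell with a median of -0.28, 13 of 13 negative, and a lower mean in 4 of 4 libraries (camera adjusted p = 5.32e-12; adjusted p = 0.17 with an estimated correlation). Adjusted over the list alone 10 were down and 0 up. MT-CO1 (ENSDARG00000063905), a subunit of cytochrome oxidase, was at 4530 ± 149 against 5340 ± 773 CPM. Erythrocyte markers fell with a median of -0.54 and a lower mean in 4 of 4 libraries (camera adjusted p = 2.96e-14; adjusted p = 0.0533 with an estimated correlation). Adjusted over the list alone 11 of 16 were down. RHAG (ENSDARG00000019253), a red cell membrane protein gene, was at 4.46 ± 2.11 against 8.91 ± 2.15 CPM. At an unadjusted p below 0.05 there were 2168 genes over the genome, and 67 ribosomal, 10 mitochondrial and 11 erythrocyte list members. DESeq2 called 88 genes and voom 0. The count of 0 became 84 without 130 dpi replicate 3, 1 without 130 dpi replicate 2, 2 without 130 dpi replicate 4 or uninjured replicate 3, 5 without uninjured replicate 1, and 91 without the 4 libraries richest in digestive-tissue RNA. The calls of these 3 lists held without each of the 9 libraries. Without uninjured replicate 5 the erythrocyte median was -0.33 and the mitochondrial one -0.15, and with 130 dpi replicate 5 included they were -0.22 and -0.18.

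**Figure D4:**
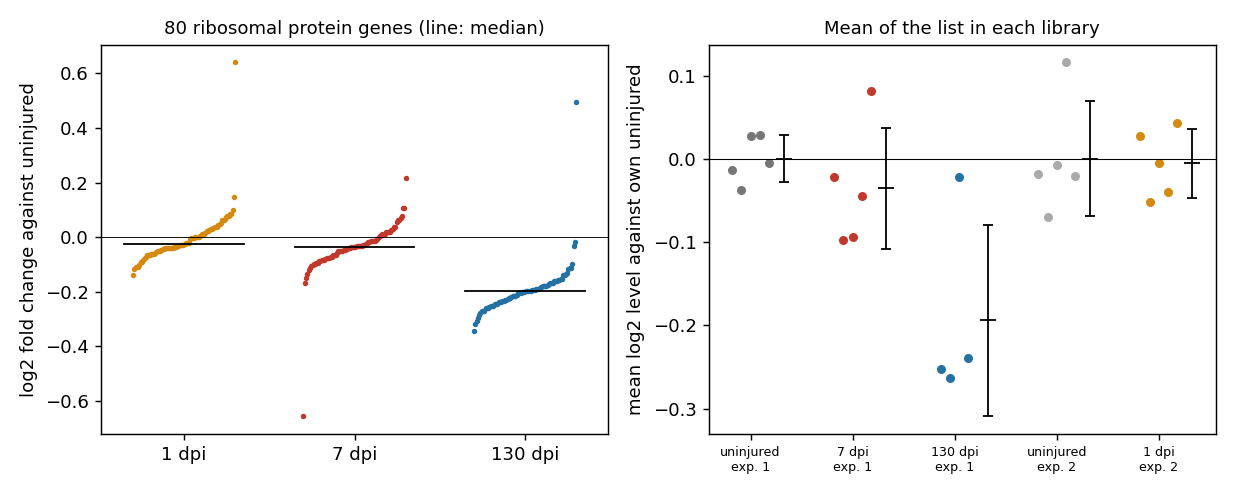
Left, log2 fold change against uninjured of each of the 80 cytosolic ribosomal protein genes at 1, 7 and 130 dpi, sorted within each time (line, median); right, mean log2 level of the list in each library, less the mean of the uninjured libraries of the same experiment (points; bars, mean and SD). The median lies at -0.20 at 130 dpi, and 130 dpi replicate 3 lies at -0.02.

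Macrophage markers rose at 130 dpi with a median of 0.45 and a higher mean in 3 of 4 libraries (camera adjusted p = 1.8e-09; adjusted p = 0.39 with an estimated correlation). The mean lay above every uninjured library in 1 of the 4. The lowest library at 130 dpi (-0.49) lay below the lowest uninjured one (-0.39). Of 30 members 0 passed edgeR's test, 10 had an unadjusted p below 0.05, and 4 were up and 1 down adjusted over the list alone. The lysosomal protease gene LGMN (ENSDARG00000039150) was at 236 ± 52.3 against 132 ± 30.6 CPM and above every uninjured library in 4 of 4 (log2 0.84 ± 0.15, adjusted p = 0.0947). The core gene of the phagocyte oxidase, cybb (ENSDARG00000056615), was at 36.7 ± 18.2 against 22.2 ± 5.38 CPM (adjusted p = 0.388). Neutrophil markers rose with a median of 0.43 and a higher mean in 3 of 4 libraries (camera adjusted p = 0.000434; adjusted p = 0.246 with an estimated correlation). Of 15 members 0 passed edgeR's test, 1 was up adjusted over the list alone and 4 had an unadjusted p below 0.05. Inflammatory cytokines and NF-kB targets rose with a median of 0.22 and a higher mean in 3 of 4 libraries (camera adjusted p = 4.44e-05; adjusted p = 0.333 with an estimated correlation). Of 38 members 0 passed edgeR's test, 9 had an unadjusted p below 0.05 and 4 were up adjusted over the list alone. Among them were the collagenase gene mmp13a (ENSDARG00000012395; 1.01 ± 0.72 against 0.131 ± 0.0746 CPM) and ACOD1 (ENSDARG00000069844), the itaconate enzyme of activated macrophages (25.2 ± 18.6 against 5.19 ± 3.77). The others were the chemokine gene cxcl19 (ENSDARG00000102776; 7.76 ± 7.01 against 0.764 ± 1.29) and tnfb (ENSDARG00000013598; 1.45 ± 0.80 against 0.547 ± 0.257). These 3 calls held without each of the 9 libraries. The macrophage median became 0.67 and 0.20 without 130 dpi replicates 3 and 4, and the neutrophil median 0.24 and 0.23 without 130 dpi replicates 1 and 4. Without the 4 libraries richest in digestive-tissue RNA the macrophage median was 0.715 and the inflammatory one 0.38.

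Sertoli cell markers fell at 130 dpi with a median of -0.30 and a lower mean in 3 of 4 libraries (camera adjusted p = 3.03e-06; adjusted p = 0.17 with an estimated correlation). Of 21 members 0 passed edgeR's test and 9 had an unadjusted p below 0.05. Adjusted over the list alone 1 was down, a copy of the tight junction gene CLDN11 (ENSDARG00000030723; 7.72 ± 1.62 against 12.2 ± 3.62 CPM). Another CLDN11 copy on the list (ENSDARG00000020031) was not. The anti-Mullerian hormone gene amh (ENSDARG00000014357), which restrains germ cell differentiation, was at 334 ± 97.4 against 595 ± 229 CPM (edgeR adjusted p = 0.483). Epigenetic regulators rose with a median of 0.06 and a higher mean in 3 of 4 libraries (camera adjusted p = 0.000436; adjusted p = 0.401 with an estimated correlation). Of 60 members 0 passed edgeR's test or adjusted over the list alone, and 5 had an unadjusted p below 0.05. DNMT1 (ENSDARG00000030756), the maintenance DNA methyltransferase, was at 252 ± 12.9 against 252 ± 7.25 CPM. Endothelial markers (median -0.13, lower mean in 3 of 4 libraries; camera adjusted p = 0.00363; adjusted p = 0.489 with an estimated correlation) fell. The Leydig list fell with a median of -0.19 in 3 of 4 (camera adjusted p = 0.00574; adjusted p = 0.401 with an estimated correlation). The glucocorticoid response list fell with -0.09 in 4 of 4 (camera adjusted p = 0.0159; adjusted p = 0.333 with an estimated correlation). In these 3 lists 0 members passed edgeR's test, 1, 0 and 1 were down adjusted over the list alone and 4, 3 and 5 had an unadjusted p below 0.05. The other genes named by the rule, none past the test, were STOML3 (ENSDARG00000057035), PRDM1 (ENSDARG00000002445), the lysosomal protease gene CTSC (ENSDARG00000101334) and prcc (ENSDARG00000063252), higher by log2 0.36 to 1.61. Those lower were PIK3IP1 (ENSDARG00000003281), EFNA1 (ENSDARG00000018787), tmem14a (ENSDARG00000095157) and krt15 (ENSDARG00000036840), with log2 changes from -0.90 to -0.38. The endothelial and Leydig calls ended without 130 dpi replicate 3 (adjusted p = 0.273 and 0.127) or uninjured replicate 5 (0.172 and 0.0986). The endothelial call also ended with 130 dpi replicate 5 included (0.289). The glucocorticoid call ended without 130 dpi replicate 1 (0.0732), 130 dpi replicate 3 (0.276), uninjured replicate 1 (0.0947), uninjured replicate 3 (0.117) or uninjured replicate 5 (0.0776). All 3 ended without the 4 libraries richest in digestive-tissue RNA (0.404, 0.176 and 0.321). The Sertoli median became -0.14 without uninjured replicate 5 and -0.185 with 130 dpi replicate 5 included. The endothelial median became -0.07, -0.26 and -0.04 without 130 dpi replicates 3 and 4 and uninjured replicate 5, -0.05 without the 4 libraries, -0.01 with 130 dpi replicate 5 and -0.07 with the block. The Leydig median became -0.34 and -0.07 without 130 dpi replicate 4 and uninjured replicate 5, -0.09 with 130 dpi replicate 5 and -0.08 with the block. The glucocorticoid median changed sign without uninjured replicate 5 (0.02). It was -0.17 and -0.14 without 130 dpi replicates 2 and 3, -0.05, -0.15 and -0.15 without uninjured replicates 1, 2 and 4, and -0.04 with digestive-tissue markers as a covariate.

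Compared directly, testes at 130 and 7 dpi differed in 1670 genes, 900 higher and 770 lower at 130 dpi. Macrophage markers were higher, with a median log2 difference of 0.66. Of 30 members 8 were higher and 0 lower past edgeR's test, and 15 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.69e-09; adjusted p = 0.519 with an estimated correlation). LGMN was 2.26-fold higher (236 against 104 CPM, log2 1.18 ± 0.15, adjusted p = 0.000625). SPI1 (ENSDARG00000000767), the master transcription factor of myeloid cells, was at 20.5 against 6.57 CPM (adjusted p = 0.0105) and the scavenger receptor gene marco (ENSDARG00000059294) at 41.3 against 17.8 CPM (adjusted p = 0.02). Inflammatory genes were higher, with 8 of 38 members past the test and 16 adjusted over the list alone (camera adjusted p = 1.67e-07; adjusted p = 0.475 with an estimated correlation). ACOD1 was at 25.2 against 2.78 CPM (adjusted p = 0.00578), and one PTGS2 copy (ENSDARG00000010276), the prostaglandin synthase, at 6.65 against 4.25 CPM (adjusted p = 0.00594). Neutrophil markers followed with 4 of 15 members past the test and 8 adjusted over the list alone (camera adjusted p = 0.000346; adjusted p = 0.475 with an estimated correlation). The chemokine receptor gene cxcr1 (ENSDARG00000052088) was at 6.72 against 0.567 CPM (adjusted p = 0.0088). Ribosomal protein mRNAs were lower at 130 dpi in 25 of 80 members past the test, and 44 lower and 1 higher adjusted over the list alone (camera adjusted p = 2.86e-18; adjusted p = 0.475 with an estimated correlation). Mitochondrial mRNAs were lower in 4 of 13 and 10 adjusted over the list alone (camera adjusted p = 3.7e-08; adjusted p = 0.475 with an estimated correlation). Meiosis genes were higher in 3 of 33 members past the test and 3 adjusted over the list alone (camera adjusted p = 0.0136; adjusted p = 0.56 with an estimated correlation). TEX11 was at 284 against 209 CPM (adjusted p = 0.00253). Acute phase genes were lower in 2 of 25 members past the test (camera adjusted p = 0.0164; adjusted p = 0.694 with an estimated correlation). Liver transcripts outside that list moved beside them, with a median of -2.41 and 32 of 32 negative. Among large decreases, serpina1 (ENSDARG00000090286) and fabp10a (ENSDARG00000038439) measured 113 ± 211 and 171 ± 323 CPM at 7 dpi. At 130 dpi they measured 2.13 ± 0.605 and 5.49 ± 1.16 CPM. Among large increases, ctsl.1 (ENSDARG00000003902) measured 112 ± 222 CPM at 130 dpi against 0.754 ± 0.436 at 7 dpi. For these genes the SD exceeded the mean in the higher group. The count of 1670 became 639 and 736 without 130 dpi replicates 2 and 1, 936, 978 and 981 without 7 dpi replicates 5, 2 and 4, 311 with all 25 libraries, 433 with experiment 1 alone, 2864 with DESeq2 and 2657 with voom. Neither fit for digestive-tissue RNA was examined for this contrast, so the share of such RNA in the count is not known. The list calls of this contrast were not examined with single libraries left out.

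The changes at 1 and 7 dpi, each against its own uninjured group, differed in 94 genes, with the 1 dpi change higher in 80 and lower in 14. The change of the glucocorticoid response list was higher at 1 than at 7 dpi, with a median log2 difference of 0.35 (camera adjusted p = 3.69e-09; adjusted p = 0.0115 with an estimated correlation). Of 21 members 3 passed edgeR's test (HSD11B2, tsc22d3 and CEBPD) and 8 passed adjusted over the list alone, each with the higher change at 1 dpi. It was the 1 call among all comparisons that held with an estimated correlation. HSD11B2 differed by 1.74 ± 0.30 (SE, adjusted p = 0.00985), tsc22d3 by 2.39 ± 0.43 (0.0135), CSRNP1 by 2.47 ± 0.39 (0.00665) and rasd1 by 3.45 ± 0.57 (0.00665). MYCN went the other way, with a difference of -2.27 ± 0.28 (edgeR adjusted p = 0.000702). The change of immediate early genes, though not always their level, was higher at 1 than at 7 dpi in 3 of 32 members past the test. Adjusted over the list alone these were 9 (camera adjusted p = 4.97e-05; adjusted p = 0.376 with an estimated correlation). Day and experiment were confounded in this contrast, and the uninjured levels differed. The glucocorticoid response list was lower in the uninjured testes of experiment 2, by a median larger in size than the 0.35 of this contrast. A difference between the times can therefore not be told apart from one between the uninjured groups. HSD11B2 and tsc22d3 were lower in the uninjured testes of experiment 2 than of experiment 1, by log2 -1.01 ± 0.21 and -1.06 ± 0.30 (edgeR adjusted p = 0.000455 and 0.00571). The count of 94 became 337 without uninjured replicate 5 of experiment 1, 53 and 60 without 7 dpi replicates 5 and 4, 525 with DESeq2 and 330 with voom.

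Across all 26648 genes, which are not independent replicates, the log2 changes at 7 and 130 dpi had a Pearson correlation of -0.01 (Spearman 0.02). It became 0.222 with all 25 libraries and 0.293 over the genes called at either time. Since 0 genes were called at 130 dpi, the last set was chosen by its change at 7 dpi. Neither that set nor the fit of 25 libraries was simulated without change. Both times share the 5 uninjured libraries of experiment 1, and in 20 simulations without any change this alone gave 0.46. The covariance was -0.0024 against 0.0419 simulated, a difference of -0.0443. Each gene was simulated on its own, without structure between libraries, so no effect of the injury can be read from that difference. With separate uninjured libraries for each time, the mean correlation over 20 splits was -0.23, ranging from -0.56 to 0.08. The changes at 1 and 7 dpi, which have separate controls, had a correlation of -0.11 (Spearman -0.02; 0 simulated), and those at 1 and 130 dpi of -0.01.

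Several groups that the design could have moved were not called in any injured group. Spermatogonia markers had medians of 0.00, 0.06 and 0.01 at 1, 7 and 130 dpi (camera adjusted p = 0.666, 0.483 and 0.911). Genes of the cell cycle and DNA replication had medians of 0.01, 0.03 and 0.00 (0.935, 0.197 and 0.66), and the heat shock and unfolded protein response 0.01, 0.03 and -0.04 (0.613, 0.489 and 0.49). Lymphocyte markers had medians of -0.03, -0.01 and 0.05 (0.81, 0.817 and 0.911), and the hypoxia response 0.08, 0.03 and -0.06 (0.0663, 0.571 and 0.168). Median, mean and test did not differ in sign for any called list, but did for 3 lists not called at 1 dpi (heat shock, cell cycle, and ciliated epithelium and kidney), 3 at 7 dpi (hypoxia, oocyte and ovary, and transforming growth factor beta) and 4 at 130 dpi (acute phase, JAK-STAT, circadian clock and lymphocyte).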

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

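The fit without uninjured replicate 5, the scalings and the spermatogonia markers were chosen after the results were seen. So were the regroupings of lists between time points and between uninjured groups. The bounds of the other tests were written down before their values. They used lists of liver, clock and oxidative phosphorylation genes that were chosen after the data were examined. Each bootstrap SD below resampled the genes of a list, which are correlated, and holds no spread between libraries. What is read from it carries that limit.

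The acute phase and complement list was higher at 7 dpi, with a median log2 change of 2.33. The tables argue against a shift shared by the injured testes, since 3 of 5 libraries lay above every uninjured library. Liver tissue carried over with the testis is a possible explanation, since liver transcripts outside the list had a median of 2.24 (bootstrap SD 0.28) and moved in the same libraries. Without 7 dpi replicate 4 the median of the acute phase list was 0.42. A response of the testis itself in those libraries stays open.

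The immediate early, interferon and glucocorticoid lists were lower at 7 dpi, with a median of -0.16 over their 89 members. The tables argue against uninjured replicate 5 alone, without which the median was -0.14 (bootstrap SD 0.058). The medians of the 2 phases of the circadian clock differed by -0.09 (bootstrap SD 0.096). The bound of 0.3 written for them was wider than the shift of -0.16 itself, so the time of day of sampling cannot be told apart from an effect of the injury. An effect of the injury could not be told from handling or cohort, which were not varied within the group. Of the list members, FKBP5, tsc22d3, KLF9 and CSRNP1 had higher means in the uninjured testes of experiment 1 than in every other group. HSD11B2 was highest at 1 dpi. For the former genes a high level in that uninjured group cannot be told apart from a fall after injury.

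Ribosomal protein mRNAs were lower at 130 dpi. The tables argue against fewer spermatogonia only as far as their markers show, with a median of 0.015 (bootstrap SD over genes 0.03). The highest median over 3 scalings was -0.197, but the scalings moved the median of all genes by at most 0.001, so the scaling cannot be told apart from a change of these mRNAs. A loss of short transcripts in general could explain part of it, since nuclear-encoded oxidative phosphorylation subunits had a median of -0.121 (bootstrap SD 0.008) against a bound of -0.099. These subunits also share a function, so their decrease cannot tell a loss of short transcripts from a joint change of those genes. Gene length was not tested, and an effect of injury or of the age of the fish stays open.

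The libraries were also regrouped at random, up to 100 times for each count, the real grouping included. At 1 dpi 11 of 100 groupings called at least as many genes as the real 1, with 20 as the highest other, so chance cannot be excluded for that count. At 7 dpi 5 of 100 called at least 326, with 625 as the highest other, so chance cannot be excluded. Groupings with 502, 458 and 377 genes differed from the real one only by exchanging uninjured replicate 5 with 1 library at 7 dpi. At 130 dpi the real grouping called 0, which all 100 reach by construction, so nothing on chance can be read from that count. The highest other grouping called 1268, which points to a structure of the samples whose cause was not tested. For the lists, 74 of 100 groupings called at least 6 at 1 dpi (highest other 17), 42 at least 11 at 7 dpi (19) and 53 at least 11 at 130 dpi (21), so chance cannot be excluded for these counts. For 130 against 7 dpi 1 of 100, the real one, called 1670 genes and the highest other 301. These regroupings left out 130 dpi replicate 5, which had been set apart by its expression. On the first principal component of experiment 1 it lay at -29.41, beside 7 dpi libraries at -43.51 to -11.75. The other 130 dpi libraries lay at 16.92 to 27.81. No regrouping was run with replicate 5 included, so the count was tested only without it. For 1 against 7 dpi 1 of 100 called 94 with 14 as the highest other. For the uninjured groups 1 of 100 called 13844 with 6163 as the highest other. A chance arrangement of the libraries used is therefore unlikely for these 3 counts of genes. Their counts of lists do not exclude chance, since 16 of 100 groupings called at least 16 for 130 against 7 dpi (highest other 19), 42 at least 10 for 1 against 7 dpi (17) and 85 at least 8 for the uninjured groups (20).

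Single libraries stood far from the others of their group by Dixon's test in 12 of 126 groups, where chance marks about 1 in 20, or 6.3. On the log2 CPM scale these were tex2l in uninjured replicate 4 (2.78; others 1.44 to 1.71), GADD45G in 7 dpi replicate 1 (3.66; 1.71 to 2.21), CSRNP1 in uninjured replicate 5 (5.54; 4.08 to 4.49) and RPS13 in 130 dpi replicate 3 (8.2; 8.03 to 8.05). Among list levels, the Leydig list stood apart in 1 dpi replicate 3 (0.3; 0.12 to 0.17), uninjured replicate 9 (-0.47; 0.07 to 0.16), uninjured replicate 5 (0.24; -0.11 to -0.02) and 130 dpi replicate 4 (0.09; -0.25 to -0.2). Uninjured replicate 5 also stood apart in Sertoli cell markers (0.27; -0.1 to -0.03) and mitochondrial mRNAs (0.44; -0.15 to -0.02), and 130 dpi replicate 3 in ribosomal protein mRNAs (-0.02; -0.26 to -0.24). The total of 1 dpi replicate 2 was 28.53 M (52.25 to 56.76).

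Differences between time points were tested within the fit. The changes at 1 and 7 dpi differed in 94 genes and 10 lists, and those at 130 and 7 dpi in 1670 genes and 16 lists. Among the named genes the log2 difference of 1 from 7 dpi was 1.74 for HSD11B2, -2.27 for MYCN, 4.62 for NTS, 3.45 for rasd1, 2.45 for GADD45B, 2.67 for NUAK1, 2.39 for tsc22d3, 2.47 for CSRNP1 and 1.04 for EFNA1. That of 130 from 7 dpi was 1.24 for MFAP4, -2.94 for itih3b.2, -1.98 for slc7a2, -2.33 for kcnh6b, -0.81 for MYCN, -1.63 for slc25a24l, -1.52 for ifnlr1, -1.35 for RBFOX3, -1.6 for sned1 and -1.31 for tex2l. It was 3.15 for ppp1r14d, 1.32 for GADD45B, 1.18 for LGMN, 1.87 for STOML3, 0.85 for CTSC, -0.32 for PIK3IP1 and -0.24 for RPS13.

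In 130 dpi replicate 5, which the comparisons leave out, the acute phase list lay at 0.65, above the highest uninjured library at 0.32. Its heat shock list lay at 0.14, above the highest uninjured library, which was also 0.14 to 2 decimals.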

How the results depend on the processing

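Leaving out each library in turn gave 0 to 45 genes at 1 dpi, 143 to 1167 at 7 dpi, 0 to 84 at 130 dpi, 639 to 1636 for 130 against 7 dpi and 53 to 337 for 1 against 7 dpi, and 3 to 10, 9 to 14 and 10 to 14 lists at 1, 7 and 130 dpi. In that order DESeq2 gave 82, 1019, 88, 2864 and 525 genes. Its false calls were more frequent on simulated data, which were drawn with the spread estimated by edgeR. Voom with quality weights gave 4, 1215, 0, 2657 and 330. A single experiment, with fewer libraries to estimate the spread, gave 9 genes at 1 dpi (0 shared), 89 at 7 dpi, 0 at 130 dpi and 433 for 130 against 7 dpi. A minimum of 2-fold left 108 genes at 7 dpi, 530 for 130 against 7 dpi and 41 for 1 against 7 dpi by construction. With 130 dpi replicate 5 included the counts were 208 at 7 dpi and 311 for 130 against 7 dpi. Without the 4 libraries richest in digestive-tissue RNA, an alternative chosen after the data were seen, they were 81 at 7 dpi and 91 at 130 dpi. This alternative was not examined for the differences between time points. With an estimated correlation 0 lists were called at 1, 7 and 130 dpi, and with fry 0, 1 and 2. The correlation of the changes at 7 and 130 dpi was 0.222 with all 25 libraries and 0.293 over genes called in either, against -0.013. That at 1 and 7 dpi was -0.29 over genes called in either, against -0.112. For 7 and 130 dpi the genes called were chosen by the change at 7 dpi alone, and no value without change was simulated for them. Where no construction is named, the cause was not tested. Of 143 values of named genes, DESeq2 left 107 on the same side of the threshold and moved 36 past it, and all 25 libraries left 137 and moved 6 out; none changed direction. With the replicate number as a block the counts were 407 genes at 7 dpi, 2 at 130 dpi and 935 for 130 against 7 dpi. Over 13 pairs with the same number the correlation ran from -0.202 to 0.114, with a median of 0.027 against -0.036 for other pairs. In 3 of these pairs the library of the same number was the best match. The numbers thus gave no clear pairing of the libraries, but a weak one cannot be excluded. For 1 dpi alone no paired analysis was possible, because that group shares no number with its uninjured libraries. In simulated data edgeR recovered 52.2, 56.7 and 53.7% of 1.5-fold changes of better counted genes at 1, 7 and 130 dpi, which limits small changes at each time.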

Other observations

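The mean levels of FKBP5, CSRNP1, rasd1, GADD45B, tsc22d3 and KLF9 were higher in the uninjured testes of experiment 1 than in each other group, although single libraries overlapped for all but CSRNP1, and FKBP5 and KLF9 did not pass edgeR's test at 7 dpi (adjusted p = 0.113 and 0.102). FKBP5 averaged 104 CPM in those 5 libraries and 26.1 at 7 dpi, 33.3 at 130 dpi, 25.7 in the uninjured libraries of experiment 2 and 85.0 at 1 dpi. CSRNP1 averaged 25, 7.64, 11.9, 6.76 and 11.4 CPM in the same order, and rasd1 5.67, 1.37, 1.88, 1.2 and 3.15. GADD45B averaged 60.0, 15.5, 38.7, 22.3 and 31.5 CPM, tsc22d3 79.1, 23.3, 45.1, 37.8 and 58.3, and KLF9 29.7, 19.5, 20.1, 18.7 and 26.9. HSD11B2 averaged 219, 184, 174, 109 and 305 CPM, so its uninjured level also differed, while its highest mean was at 1 dpi. Between the uninjured groups of the 2 experiments the log2 difference was -2.02 ± 0.61 (SE) for FKBP5 (edgeR adjusted p = 0.00947), -1.89 ± 0.28 for CSRNP1 (1.03e-05), -2.24 ± 0.41 for rasd1 (8.34e-05), -1.01 ± 0.21 for HSD11B2 (0.000455), -1.06 ± 0.30 for tsc22d3 (0.00571) and -0.67 ± 0.18 for KLF9 (0.00409). The glucocorticoid response list was lower in the uninjured testes of experiment 2 in 14 of 21 members past the test, with a median of -0.67 (camera adjusted p = 0.00458; adjusted p = 0.519 with an estimated correlation).

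Transcripts of digestive organs varied between pools. Exocrine pancreas transcripts lay 4.39 (mean log2 level over the uninjured mean of experiment 1) in uninjured replicate 1 of experiment 1, 2.43 in 7 dpi replicate 4 and 2.42 in 130 dpi replicate 3, and intestine transcripts 1.85 in 130 dpi replicate 3. The medians of the pancreas list were -0.95, -2 and -1.48 at 1, 7 and 130 dpi, with 0 of 15 members past edgeR's test at each time.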
